A study of Chlorella vulgaris with 6 samples.

How the data were processed

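Messenger RNA was measured in 6 libraries of the green alga Chlorella vulgaris: 2 of wild type, 2 of the mutant UV-715 and 2 of the mutant EMS-25. Per the labels' protocols, RNA came from cultures of 14 days in stationary phase (optical density of 5 at 680 nm), was enriched for polyadenylated transcripts, and was sequenced as paired reads of 75 bp on a MiSeq instrument. The labels call the libraries of a strain biological replicates and do not say that each came from its own culture, so p-values measure the spread between these libraries, which could be partly technical.

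The deposited table gives a normalised expression signal for 18600 features in each library. The submitters' processing notes name FastQC 0.11.5, Trimmomatic 0.32, RSEM and edgeR, without roles. The values have 3 decimals, and the 6 library sums lie between 970974 and 1029717 with a geometric mean of 1000000, which is the form of a transcripts-per-million value multiplied by a scaling factor per library. The table is therefore treated as a signal that the authors had scaled between libraries, and no count model was used. Feature IDs name an assembly cluster, a component and a gene, in the form that the Trinity assembler writes, and all 18600 have this form (10997 clusters, 15574 components). The assembly, its annotation and any filter are not given in the sources used here. No gene names, sequences or reference were used here, so the lists of lipid, carbon, photosynthesis, nitrogen, DNA repair and bacterial genes that had been written before the data were examined had no members to test and gave no result. Summing isoforms to genes was planned and could not be run, since the IDs already stand at gene level.

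The absolute depth of the libraries is unknown. Relative depth was read from the low values, where a feature's values in different libraries are multiples of what 1 fragment is worth for that feature. Over 3160 features used for this step, the relative depth was 1.0 and 0.243 in wild type, 1.049 and 0.492 in UV-715 and 0.988 and 0.397 in EMS-25 (replicates 1 and 2). With these depths, 84.1%, 85.8% and 85.6% of the low values of the 3 replicate 2 libraries (up to 8 fragments) lay within 0.1 of a whole number of fragments. The step recovered the depths of simulated libraries with a largest error of 0.0%. Those libraries held whole numbers of fragments by construction, so this checks the calculation and not its accuracy on the real values. No pair of libraries held identical values. At values of 1024 or more the robust SD between the libraries of a strain was 1.52, 1.81 and 1.71 times the counting noise extrapolated from values of 64 to 128 (wild type, UV-715, EMS-25), and they were not treated as a library deposited more than once. The extrapolation used values, while counting noise follows fragments, which also depend on feature length. Lengths were not known, so these ratios alone do not decide this. At 64 to 128, the variance over that of wild type was 0.49 in UV-715 and 0.7 in EMS-25. Relative depth alone predicts 0.58 and 0.69, so the spread there may be mainly technical. Separate preparations of a single RNA sample would also exceed counting noise, so the ratios do not show separate cultures.

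Features with a value of at least 1 in at least 2 libraries were kept (18096 kept, 504 left out). The log2 of the value plus a pseudocount of 1 was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend and empirical Bayes moderation. All 6 libraries entered a single fit, with strain as the only term (3 residual and 2.66 prior degrees of freedom). Tests were two-sided, and a feature was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Log2 fold changes are on the scale of the value plus 1, which understates the change of low features. Means and SDs are of the deposited values, with n = 2 per strain. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.

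The features named were chosen by a rule fixed before the data were examined: per comparison, the 2 with the highest and the 2 with the lowest log2 fold change among called features with a mean of at least 5 and with both libraries of one strain above both of the other. Features described without an ID were chosen after their values were seen. An ID ending in another gene number of the same component is called a sibling, and component sums add the values of all siblings, and cluster sums those of all components of a cluster.

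The fit was tested on simulated data made from the real levels and residuals. The residual of each library came from a feature of similar level, drawn anew for each library. A feature's own spread and deviations common to same-numbered libraries were therefore not kept. Recovery and false calls in the real data may differ. Without any change, 20 simulated data sets gave at most 2 calls in each comparison against wild type and at most 1 between the mutants. With 200 features changed per fit, 2-fold changes at a mean value of 100 or more were recovered in 89.2% of cases for UV-715 and 94.4% for EMS-25. At a mean under 30, recovery of 2-fold changes was 0.5% and 0%, and of 4-fold changes 7.5% and 8.3%. An average of 2.1 unchanged features was called per fit.

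Both mutants were compared with the same wild-type libraries, so overlaps and correlations are given beside simulated unchanged strains and beside independent lists. All 6 libraries were redrawn in the simulation, wild type included, and both simulated mutants were compared with the same simulated wild type. Draws numbered 100 for correlations over all features. They numbered 20 for the correlation at a mean of at least 100, overlaps of calls and lists of the observed lengths. Alternatives covered the pseudocount, the filter, the scaling, the variance trend, the replicate number as a block, the libraries in the fit, effect size thresholds and leaving out each library. Library weights, high features alone, component sums and cluster sums were added after the data were seen.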

Results

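The transcriptomes of wild-type Chlorella vulgaris and of 2 mutants with high lipid content, UV-715 and EMS-25, were compared in stationary phase, with 2 libraries per strain. The labels describe UV mutagenesis at 254 nm followed by picking of single colonies, and call EMS-25 an EMS mutant. Of 18600 assembled features, 12360 had a value above 0 in all 6 libraries and 165 were listed at 0 in all 6. Replicate 1 and 2 libraries listed 1376 and 4177 features at 0 in wild type, 1406 and 2826 in UV-715, and 1485 and 3204 in EMS-25. Wild type replicate 2, which had the most features at 0, also had the lowest relative depth (0.243 of wild type replicate 1). The features carry IDs and no gene names, so the transcripts below are described by level and by strain.

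Abundant transcripts separated the strains clearly. Over the 1610 features with a mean value of at least 100, Pearson's r of log2 values across features was between 0.9904 and 0.9914 within a strain and between 0.9085 and 0.9487 across strains. For these features 90.3% of the variance lay between strains, where 40% is the share that unrelated libraries would give. The first principal component (58.7% of the variance) set UV-715 apart from wild type, with EMS-25 between them, and the second (31.6%) set EMS-25 apart from both. Over all 18096 features kept, the share between strains was 47.1% and the first component set wild type replicate 2 apart from the other libraries. The robust SD of the log2 ratio of the replicates fell from 0.99 at values of 4 to 8 to 0.055 at 1024 or more in wild type, from 0.88 to 0.046 in UV-715 and from 0.94 to 0.053 in EMS-25.

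**Figure D1:**
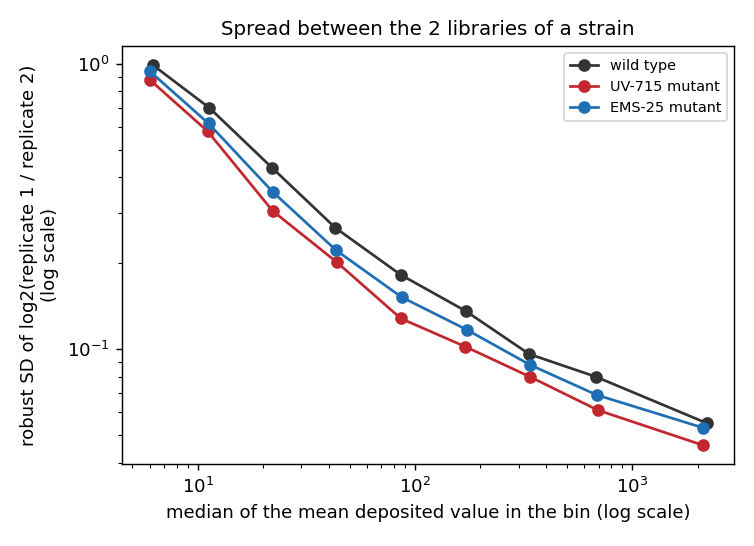
Robust SD of the log2 ratio of replicate 1 to replicate 2 (vertical, log scale) against the median of the mean deposited value in bins of level (horizontal, log scale), one line per strain. The spread is widest in wild type in every bin drawn and falls to between 0.046 and 0.055 at values of 1024 or more.

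UV-715 differed from wild type in 762 features, of which 339 were higher and 423 lower. The feature with the smallest p, chosen after its values were seen, stood at 279 ± 15.8 in wild type and 2135 ± 20.8 in UV-715 (SD, n = 2 each), a 7.65-fold higher value (log2 fold change 2.93, SE 0.05, adjusted p 4.11e-05 by limma). TRINITY_DN2605_c0_g2 rose from 7.41 ± 0.37 to 686 ± 165 (log2 fold change 6.33, SE 0.40, adjusted p 0.00222). The other feature of its assembly component stood at 1632 ± 57.3 in wild type and 926 ± 120 in UV-715, and the sum of both was 1639 ± 57.7 against 1612 ± 44.8 (adjusted p 0.799). The division between both features also differed within EMS-25, where TRINITY_DN2605_c0_g2 had 304 and 726 and the other feature 1441 and 969 in replicates 1 and 2. TRINITY_DN1559_c0_g1 was listed at 0 in wild type and EMS-25 and had 51.8 and 57.1 in the 2 UV-715 libraries (adjusted p 0.00993). The named features that fell were TRINITY_DN7858_c0_g1, with 658 and 624 in wild type and 0 in both UV-715 libraries (adjusted p 0.00103), and TRINITY_DN6806_c0_g1, with 97.8 and 65.2 in wild type and 0 in every mutant library (adjusted p 0.00704).

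Most of these changes were moderate, with a median absolute log2 fold change of 0.76 among the calls. At least 2-fold were 278 calls (112 higher, 166 lower), and at least 8-fold were 47 (18 higher, 29 lower). The higher features together held 6.49% of the summed signal in wild type and 10.5% in UV-715, and the lower ones 14.1% and 9.07%. Calls made up 31.7% of the features with a mean of 300 or more and 0.28% of those under 10, a range in which the simulated 2-fold changes were rarely recovered. An unadjusted p under 0.05 was found for 3621 features. Which direction had more calls depended on the setting: it was 434 higher and 428 lower with libraries set to the same sum, 118 and 52 without the intensity trend, 42 and 38 against a 1.5-fold threshold, and 289 and 173 without wild type replicate 1. The count was 462 and 182 without wild type replicate 1 and 2, 3 and 4 without UV-715 replicate 1 and 2, and 346 and 340 without EMS-25 replicate 1 and 2. The 4 named features all lost their calls without either UV-715 library (adjusted p between 0.0573 and 0.1), 1 lost it without wild type replicate 1 and 2 without wild type replicate 2, while their log2 fold changes moved by at most 0.29.

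EMS-25 differed from wild type in 208 features, and here the higher ones were in the majority (141 higher, 67 lower). TRINITY_DN6031_c7_g3 was listed at 0 in wild type and UV-715 and had 256 and 210 in the 2 EMS-25 libraries (adjusted p 0.00481 by limma). TRINITY_DN5745_c0_g2 was listed at 0 in wild type, with 114 and 109 in EMS-25 and 71.1 and 35.1 in UV-715 (adjusted p 0.00298). The sum over the component of each was also higher in EMS-25, at 353 ± 49.8 against 119 ± 1.36 (adjusted p 0.00401) and at 135 ± 0.67 against 62.3 ± 1.18 (adjusted p 0.00214). The sibling of TRINITY_DN5745_c0_g2 stood lower in EMS-25, at 23.9 ± 4.38 against 62.3 ± 1.18 in wild type (adjusted p 0.371 by limma). Its lower value offset part of the rise within the component. A feature in another component of the TRINITY_DN5745_c0_g2 cluster had 47.4 ± 0.98 in wild type, 0 in both UV-715 libraries and 2.86 and 0 in EMS-25. Sums over the whole cluster were 137 ± 1.36 in EMS-25 against 110 ± 2.16 in wild type for TRINITY_DN5745_c0_g2 (3 features, adjusted p 0.0973) and 1444 ± 96.9 against 1326 ± 1.81 for TRINITY_DN6031_c7_g3 (41 features, adjusted p 0.369). The change of a single feature can be lost in a sum over 41. TRINITY_DN7858_c0_g1 and TRINITY_DN6806_c0_g1 fell here as well: the first had 0.54 and 1.97 in EMS-25 (adjusted p 0.00293) and the second was listed at 0 (adjusted p 0.0188). The feature with the smallest p was the one of the UV-715 comparison, at 1388 ± 29.7 in EMS-25, 4.98-fold above wild type (log2 fold change 2.31, SE 0.05, adjusted p 0.000293).

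The median absolute log2 fold change of the EMS-25 calls was 0.69, and 61 were at least 2-fold (40 higher, 21 lower). The higher features held 3.75% of the signal in wild type and 5.74% in EMS-25, and the lower ones 3.27% and 2.18%. Calls made up 13.4% of features with a mean of 300 or more, and 2448 features had an unadjusted p under 0.05. This count was the least stable: 36 and 4 features were called without wild type replicate 1 and 2, 0 without either UV-715 library, 6 and 10 without EMS-25 replicate 1 and 2, and 7 in a limma fit of wild type and EMS-25 alone. All 4 named features lost their calls without wild type replicate 2 or without either UV-715 library, 2 without wild type replicate 1 and 3 without either EMS-25 library (adjusted p between 0.0548 and 0.171), while their log2 fold changes moved by at most 0.48. The fit of wild type and EMS-25 alone ended the calls of TRINITY_DN5745_c0_g2 (limma adjusted p 0.0675), TRINITY_DN7858_c0_g1 (0.0667) and TRINITY_DN6806_c0_g1 (0.0994). A pseudocount of 0.1 ended that of TRINITY_DN6806_c0_g1 (0.0698). The feature with the smallest p lost its call without UV-715 replicate 1 or 2. Its log2 fold change stayed at 2.312, since those libraries belong to neither strain compared.

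**Figure D2:**
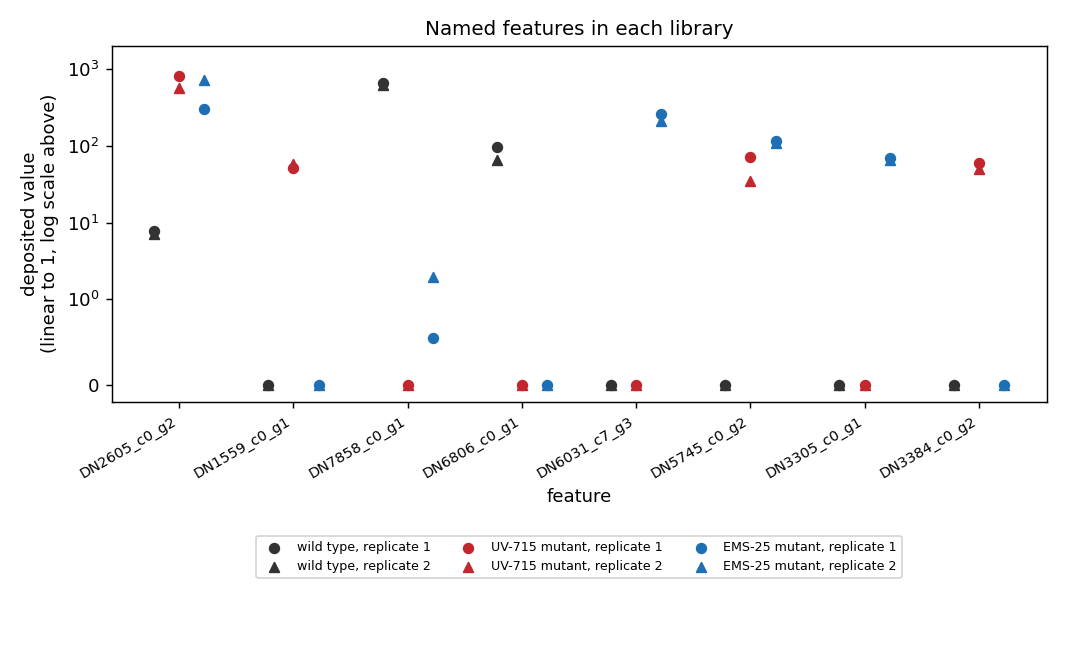
Deposited value (vertical axis, linear up to 1 and logarithmic above) of the 8 named features in each of the 6 libraries, with circles for replicate 1 and triangles for replicate 2. TRINITY_DN7858_c0_g1 stands at 658 and 624 in wild type and below 2 in the mutants, and 5 of the features are above 0 in a single mutant or in wild type alone.

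The mutants also differed from each other. Between EMS-25 and UV-715, 841 features were called, 501 higher in EMS-25 and 340 lower. The named features that were higher in EMS-25 were TRINITY_DN6031_c7_g3 (adjusted p 0.00198 by limma) and TRINITY_DN3305_c0_g1, which had 68.3 and 65.9 in EMS-25 and was listed at 0 in the other strains (adjusted p 0.00706). Those lower in EMS-25 were TRINITY_DN1559_c0_g1 (adjusted p 0.00914) and TRINITY_DN3384_c0_g2, with 59.1 and 49.2 in UV-715 and 0 in the other strains (adjusted p 0.00938). The sibling of the latter had 6.68 ± 0.75 in UV-715, 54.5 ± 6.18 in EMS-25 and 56.9 ± 2.99 in wild type, and the sum of both features did not differ between the mutants by the test (60.8 ± 7.74 and 54.5 ± 6.18, adjusted p 0.575). The feature with the smallest p, chosen after its values were seen, had 43.7 ± 0.33 in UV-715, 81.5 ± 2.0 in wild type and 223 ± 2.53 in EMS-25 (log2 fold change 2.32, SE 0.06, adjusted p 0.000466). This feature was the only one of its component. The component sum of TRINITY_DN6031_c7_g3 was 353 ± 49.8 in EMS-25 and 124 ± 10.1 in UV-715 (adjusted p 0.00147 by limma). Sums over whole clusters did not pass the test for this last feature (41 features, 1444 ± 96.9 and 1256 ± 42.1, adjusted p 0.0918) or for the one with the smallest p (70 features, 5733 ± 349 in EMS-25 and 5419 ± 198 in UV-715, adjusted p 0.566). The change of a single feature can be lost in sums over so many, so these cluster sums decide nothing on it. The median absolute log2 fold change was 0.80, 316 calls were at least 2-fold (203 higher in EMS-25, 113 lower), and 3432 features had an unadjusted p under 0.05. The count was 31 and 25 without UV-715 replicate 1 and 2, and 129 and 130 without EMS-25 replicate 1 and 2, and the majority turned without EMS-25 replicate 1 (57 higher, 72 lower) and without the intensity trend (101 higher, 151 lower). Leaving out any of these 4 libraries ended the calls of the 4 named features (adjusted p between 0.0518 and 0.0917), while their log2 fold changes moved by at most 0.14.

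**Figure D3:**
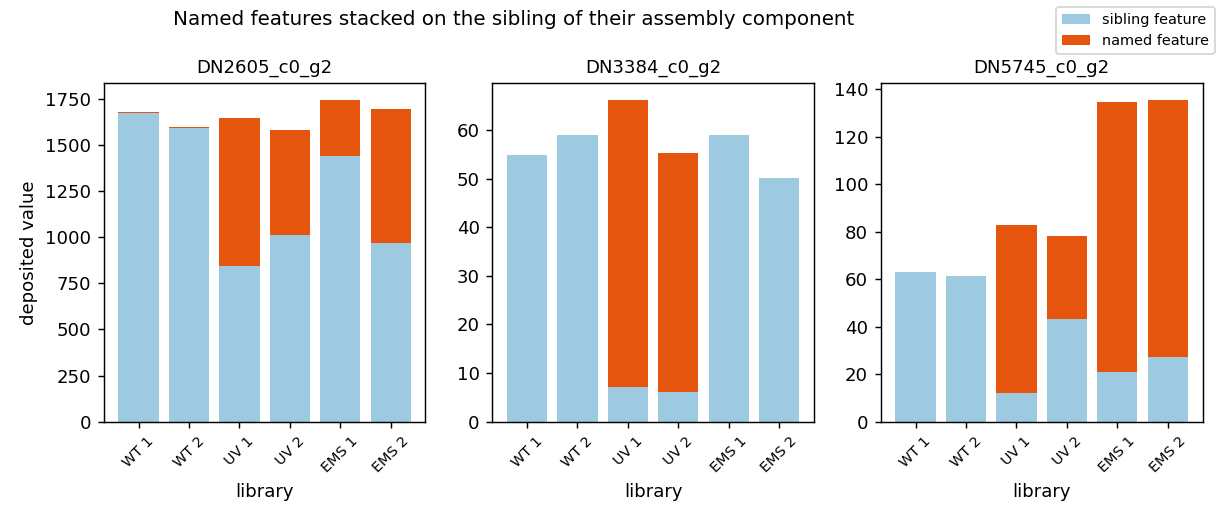
Deposited values of 3 named features (orange) stacked on the value of the other feature of their assembly component (blue), one bar per library, with WT for wild type. The height of the stack is the component sum, which averages 1639, 1612 and 1720 in wild type, UV-715 and EMS-25 for TRINITY_DN2605_c0_g2, and 62.3, 80.8 and 135 for TRINITY_DN5745_c0_g2.

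Some features were called in the same direction in both mutants. Against wild type, 56 were higher in both and 36 lower in both, and these 92 made up 44.2% of the EMS-25 calls. Independent lists of these lengths would share 2.64 and 1.57 features. Unchanged simulated mutants, compared with the same simulated wild type, shared at most 1 call, but had at most 2 calls per comparison to share. Lists of 762 and 208 features taken from them by smallest p, a comparison chosen after the data were seen, shared 99.2 in the same direction on average (84 to 113 in 20 draws). Those lists are ordered by chance and nearly all of their features fail the test that the 92 passed, so neither simulated number says how many of the 92 come from the shared controls. A further 21 were called in opposite directions, where independent lists would give 4.55. Independent lists ignore level, while the calls of both comparisons gather among high features. At a mean of 300 or more, 31.7% of features were called for UV-715 and 13.4% for EMS-25, against 0.28% and 0.02% under 10. Level alone therefore raises both kinds of overlap above 2.64, 1.57 and 4.55, and no excess over these numbers is read as a result. Because both comparisons use the same 2 wild-type libraries, part of the shared calls may come from these controls. The count of 92 was 26 and 4 without wild type replicate 1 and 2, 0 without either UV-715 library, and 6 and 9 without EMS-25 replicate 1 and 2. A difference among the 3 strains was called for 931 features by the limma F test, and for 454 without wild type replicate 2, 0 without either UV-715 library, and 219 and 227 without EMS-25 replicate 1 and 2.

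Across all 18096 features, which are not independent replicates, the log2 fold changes of the mutants had a Pearson's r of 0.51 and a Spearman's rho of 0.475. Unchanged simulated mutants gave an r of 0.589 (0.571 to 0.604), above the observed r. This does not decide on a shared response, since real changes in a single mutant widen the fold changes and can lower r. The covariance was 0.549 against 0.437 in the simulation, a difference of 0.112. With 1 wild-type library for each mutant, r was 0.04 and 0.069 over all features. Over the 1610 features with a mean of at least 100, it was 0.563 with shared controls (0.549 in the simulation) and 0.495 and 0.525 with 1 wild-type library each. The simulated 0.549 comes from library noise alone, while 90.3% of the variance of these features lay between strains, so it is no baseline for 0.563. The 0.495 and 0.525 argue against noise of the single wild-type libraries as the main source of r at this level. Splitting the wild-type libraries leaves in any level particular to the wild-type strain. These values therefore do not show a response shared by the mutants either.

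**Figure D4:**
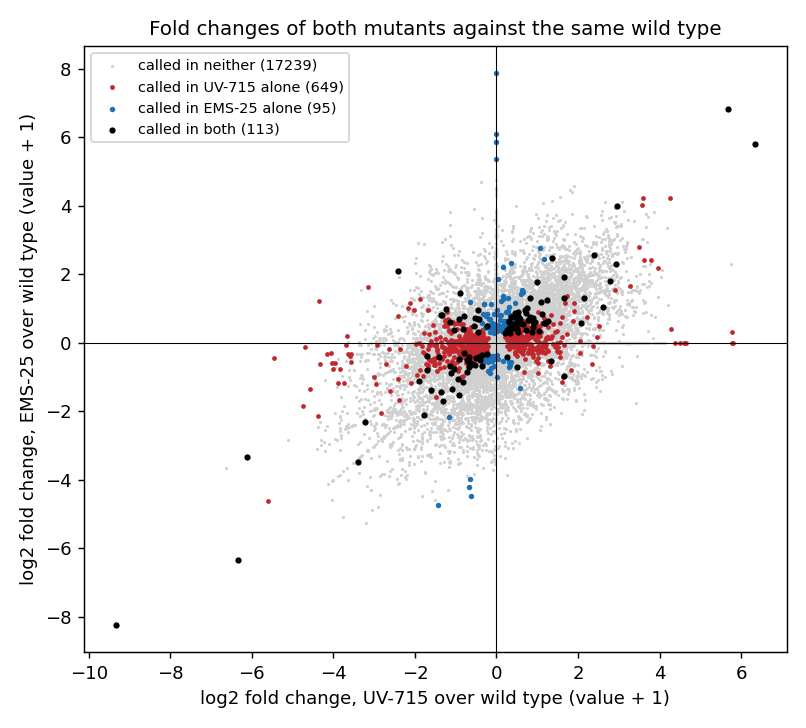
Log2 fold change of EMS-25 (vertical) against that of UV-715 (horizontal), both over wild type on the scale of the value plus 1, one point per feature tested. Black points are the 113 features called in both comparisons, red the 649 called in UV-715 alone, blue the 95 called in EMS-25 alone and grey the 17239 called in neither, and the grey diagonal cloud includes what the shared controls add.

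Some features were present in a strain and listed at 0 in another. At 1 or more in both UV-715 libraries and 0 in both of wild type were 361 features, with 182 the other way round. For EMS-25 and wild type the numbers were 213 and 184, and 245 features were on in EMS-25 and off in UV-715 against 359 the other way round. A background came from pairs that mixed the strains and, like the real pairs, held a replicate 1 and a replicate 2 library each. They gave 314 such features for UV-715 and wild type, where the real pairs gave 543, 255 against 397 for EMS-25 and wild type, and 298 against 604 between the mutants. Pairs by replicate number, which set both deep libraries against both shallow ones, gave 891, 972 and 700, more than the strains did. Asking for 20 or more, a level chosen after the data were seen, left 13, 16 and 16 in the real pairs and 2, 1 and 1 in the mixed ones. A value of 0 cannot be read as absence, since the shallow libraries list many low features at 0.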

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

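The tests in this part on sibling features were chosen after the result was seen. The effects of the mutants against wild type differed for 841 features, by the test of EMS-25 against UV-715 itself. They were called in opposite directions against wild type for 21 features, 17 of them lower in UV-715 and higher in EMS-25, and all 21 had a mean of at least 30. The widest of these, chosen after its values were seen, had 59.9 and 51.9 in wild type, 11.3 and 8.25 in UV-715 and 239 and 247 in EMS-25 (adjusted p 0.00226 and 0.00784 against wild type, limma). Its EMS-25 call was lost with each of the 6 libraries left out in turn. The log2 fold change stayed between 2 and 2.202 in these fits (2.101 with all libraries). This call was also lost without the intensity trend (limma adjusted p 0.0848) and in the fit of wild type and EMS-25 alone (0.0643). Its UV-715 call was lost without UV-715 replicate 1 or 2, with log2 fold changes of -2.617 and -2.203 (-2.41 with all libraries). The count of 21 fell to 2 without wild type replicate 1 and to 0 without each of the other 5 libraries.

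Some of the steepest changes were mirrored by a sibling in the same assembly component. TRINITY_DN2605_c0_g2, described above, is among them and among the UV-715 calls counted here. The tests were chosen after such cases were seen, so the UV-715 p-values partly rest on a case already known. Of the 13 UV-715 calls of at least 8-fold that had a sibling, 8 had siblings that together moved the opposite way by at least 50% of the feature's own change, where features of the same level drawn at random gave a mean of 2.32 and at most 6 in 2000 draws (permutation p 0.0005, the smallest these draws give; 0.0045 adjusted over the 9 tests of this kind). Calls of at least 8-fold gave 5 of 16 between the mutants (2.22 in the draws, p 0.03, adjusted 0.135), an excess that did not pass the correction, and 1 of 6 for EMS-25 (0.58 in the draws, p 0.5302), too few to decide. For most of the 95 UV-715 calls of at least 2-fold with a sibling, of 278 in all, such division is argued against, since it held for 13 (9.31 in the draws, p 0.1124; exact binomial 95% upper bound of 22.3%); calls without a sibling were not tested. Calls were counted per feature, so siblings that were both called counted separately. The draws and the binomial bound took calls as independent, so these p-values may be too small and the bound too low. Of the 9 tests, 3 on on-off features of one cluster (smallest p 0.5383), counted only partners fully on or off the other way and decide nothing on division. For the 8-fold UV-715 calls, a candidate explanation is that variants or isoforms of a gene are divided between siblings by the assembly; the component sum of TRINITY_DN2605_c0_g2 had a log2 fold change of -0.024 for UV-715, but its division also differed between the EMS-25 libraries (304 and 726, with 1441 and 969 in the sibling), which a fixed difference in sequence between strains would not give. An uneven assignment of reads between similar siblings and a shift between separate genes of one component stay open, since no sequences were used here.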

How the results depend on the processing

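Array weights, features with a mean of at least 100 alone, and component and cluster sums were chosen after the data were seen; the other alternatives were planned. Against 762, 208 and 841 calls (UV-715 and EMS-25 against wild type, EMS-25 against UV-715), 931 in the F test and 92 shared, other pseudocounts, filters and scalings, robust moderation and component sums (852, 262, 988) stayed within 1.5 times. Without the intensity trend the counts were 170, 58, 252, 218 and 23, and 65, 15 and 116 of the calls of the 3 comparisons were shared with those made with the trend. An added log2 fold change of at least 1 gave 278, 61, 316, 319 and 24, an adjusted p under 0.01 gave 279, 50, 320, 333 and 24, and a limma treat test against 1.5-fold gave 80, 22, 102 and 10 shared (no F version was run); these are stricter by construction. Fits of only the libraries compared, with fewer residual degrees of freedom, gave 337 for UV-715, 7 for EMS-25 and 5 shared. Testing only features with a mean of at least 100, and so fewer features, gave 738, 434 and 720 calls in the 3 comparisons. Of these, 394, 145 and 421 were also called with all features tested. That fit also estimated the intensity trend and the moderation anew, and this was not separated from the smaller number of tests. Quantile normalization moved the correlation of fold changes to 0.477; the cause was not tested. With 5 as the value of an on feature, on-off counts summed over the 3 comparisons and both directions were 810 in place of 1544. A feature can count more than once in these sums. The 21 opposite calls were 0 without the trend, 1 in fits of only the libraries compared and 34 in component sums.

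Leaving out each library in turn gave 3 to 462 calls for UV-715, 0 to 36 for EMS-25, 25 to 624 between the mutants, 0 to 653 in the F test, 0 to 26 shared, and correlations of 0.408 to 0.738. These fits have fewer libraries, and the lone library of a strain is taken to vary like the others. None reversed a named feature. Only component and cluster sums did, for TRINITY_DN2605_c0_g2 (-0.024 in both, adjusted p 0.799 and 0.791 by limma, within a range of 0.000865 to 0.799 over its alternatives).

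Replicate numbers are shared between the strains, but the labels do not say that a number marks a common batch. Over all features the deviations of same-numbered libraries correlated by 0.042, 0.066 and 0.052 (Pearson; ranks 0.012, 0.018 and 0.026), and over the 1610 features with a mean of at least 100 by 0.375, 0.345 and 0.429 (Pearson), with rank correlations of only 0.136, 0.088 and 0.11; this is a hint from the data and not from the design. With the replicate number as a block, the counts were 658, 172, 712, 776 and 74, and every named feature was still called. Depth limits the low features, where nearly all simulated 2-fold changes were missed. Weights per library gave 735, 171 and 1126 calls; with 2 libraries per strain they were equal within a strain.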

Other observations

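The tests on assembly clusters and on the deviations of replicates were chosen after the results were seen; those on features on in a single strain were set before. Called features of one assembly cluster moved together: 78.3% of the 138 pairs of UV-715 calls in one cluster had the same sign, against 50.5% with shuffled signs (permutation p 0.0001, the smallest that 10000 shuffles give; 0.0002 adjusted over 3 comparisons). The share was 86.7% of 15 pairs for EMS-25 (p 0.0253, adjusted 0.0253) and 83.5% of 158 pairs between the mutants (p 0.0001). Fragments of one transcript, related transcripts or shared regulation may each give this.

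UV-715 had the most features of its own. At 5 or more in both libraries and listed at 0 in the other 4, there were 96 features in UV-715, 26 in EMS-25 and 13 in wild type. Unequal depth alone is argued against, since the replicate 1 libraries, of nearly equal depth, gave 234, 96 and 108, a ratio of 2.17 to the next strain, and on-off features as a whole exceeded those of mixed pairs of equal make-up by at least 1.56 times, although pairs by replicate number gave more (891, 972 and 700), so absence in shallow libraries adds many. The excess was limited to low values, which may be stray fragments near the detection limit: at 20 or more there were 2 in UV-715 (TRINITY_DN1559_c0_g1 and TRINITY_DN3384_c0_g2), 6 in EMS-25 and 1 in wild type (TRINITY_DN6806_c0_g1), a ratio of UV-715 to EMS-25 of 0.33. That ratio rests on few features. The median value of the 96 features was 10.1, so transcripts truly present at low levels would also be lost at 20. The ratio therefore does not tell stray fragments from such transcripts. RNA of another organism in unequal shares is argued against only weakly. Over the 96 features, the log2 ratio of the UV-715 replicates differed by 0.009 (bootstrap error 0.18) from that of other features of their level. This lay within the 0.25 set beforehand, inside by 1 error and not by 2. Features had to reach 5 in both UV-715 libraries, so those that unequal shares lowered below 5 in a library were not seen. Equal shares stay open.

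At a mean of 500 or more, same-numbered libraries of different strains deviated together, with rank correlations of at least 0.334 over 278 features, which argues against a few extreme features at that level. At a mean of 100 or more the rank correlations were 0.136, 0.088 and 0.11 beside Pearson values of 0.375, 0.345 and 0.429, so a few extreme features may carry the latter. Whether the lower depth of the replicate 2 libraries or a common batch is behind the pattern at 500 or more cannot be told apart: the slope on the other strains was steeper by 0.183 (bootstrap error 0.137) where the depth gap was widest. No biological explanation was tested.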
